A study of Homo sapiens with 6 samples.

How the data were processed

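RNA was measured in 6 libraries of the SEM line, 3 transfected with duplexes against the back-splice junction of AK_8_2 (KD) and 3 with a non-targeting duplex (NC). Per the labels' protocols, cells underwent a reverse transfection with a lipid reagent and a forward transfection 24 h later, total RNA was extracted and checked for integrity, libraries were made with a total RNA kit that depletes globin transcripts, and sequencing was done on an Illumina NextSeq instrument. The labels describe the replicates as independent. The p-values of single genes rest on the spread between these 6 libraries. Groups and replicate numbers come from the sample titles.

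The deposited files hold whole-number read counts per Ensembl gene, 1 file per library, as written by htseq-count. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.10a, HTSeq 0.11.1 and DESeq2 were used on the hg38 build. The annotation release, the strand setting of the counting, the treatment of reads aligned to several places and any trimming are not given in the sources used here. Each file lists 62703 gene IDs and 5 summary lines that name no gene. These lines (no annotated feature, ambiguous, below quality, unaligned, aligned to several places) were left out of library sizes and tests; together with the gene counts they give the shares of records reported. Gene counts made up 33.8%, 60.2% and 47.8% of the records in KD replicates 1, 2 and 3 and 33.5%, 59.1% and 53.3% in NC replicates 1, 2 and 3. Because reads aligned to several places are in a summary line of their own, genes with near-identical copies are counted only from reads that the aligner placed uniquely, and without a known strand setting a gene cannot be told apart from an overlapping antisense gene.

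Of the IDs, 62686 were in the gene name table used and 42342 had a symbol other than an Ensembl name. Coordinates, gene types, lengths and GC content come from GENCODE 29 (GRCh38), which held 58264 of the IDs; it may differ from the annotation of the counting. Libraries of the same group were compared with a chi-square test of their counts, and all pairs differed by more than sampling noise (chi-square per degree of freedom 23.6 to 96.2), so all 6 were kept.

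The main comparison used edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, robust quasi-likelihood fit, quasi-likelihood F test) on the counts as deposited, with group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold; 16929 genes were tested. Log2 fold changes are KD over NC, with standard errors and 95% intervals from the same fit. CPM values use TMM-normalised library sizes, and differences within a pair are between log2 CPM values with a prior count of 2. Totals of 14750579 to 26694160 counts per library set the precision for low genes. Gene lists were tested with camera and fry of limma 3.58.1 on log2 CPM, camera with a preset inter-gene correlation of 0.01, over the 24 of 26 lists with at least 5 tested members, and their medians were set against 10000 random lists matched on mean expression. Camera compares a list with the other tested genes. Its preset correlation is a fixed value, so the p-values with it do not measure how members of a list vary together between these libraries. The shares of random lists with a lower median are not adjusted over the lists and take members as varying independently. The lists, tests, alternatives and rule for naming genes were fixed before the data were examined.

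The groups share replicate numbers. The deviations of log2 CPM from the group means correlated at 0.89, 0.62 and 0.61 across genes between KD and NC libraries numbered 1, 2 and 3, each above the limit of 0.1 set for treating the numbers as pairs, so values with the replicate number as a block (the paired fit) are given beside the results they change. The labels do not state a pairing, KD replicate 2 and NC replicate 3 correlated at 0.59 and KD replicate 3 and NC replicate 2 at 0.55, so the pairing rests mainly on replicate 1. The correlations and both fits were first computed together, and the decision followed the stated limit. The blocked fit had a biological coefficient of variation of 0.0683 against 0.372 without the block. Its p-values rest on the spread that remains once the replicate numbers are fitted.

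Genes were named by a rule: KMT2A and AFF1 always; among called genes with a symbol, up to 10 rising and 10 falling with the smallest p and up to 5 in each direction with the largest change, a mean CPM of at least 1 and no overlap between groups; per list, up to 4 called members or, with none, the 2 with the smallest p; and where nothing passed in a direction, the 5 with the smallest unadjusted p, said not to pass. Since nothing passed in the main fit, the same rule was repeated on the paired fit, a step chosen after its calls were seen, and further paired calls are named in the text as outside it. A gene called in the paired fit is counted but not reported here by name.

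The edgeR fits with and without the block were first tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 50 genes seeded at each of 1.25-, 1.5-, 2- and 4-fold. The list tests, DESeq2, limma-voom and the 1.2-fold minimum were not tested in this way. The paired fit recovered 30%, 50%, 80% and 90% of these and called 17 of 16729 unchanged genes; the fit without the block recovered 0%, 0%, 16% and 56% and called 0.

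The alternatives tried were relative log expression factors, upper-quartile factors and library totals alone; no filter and a stricter filter (CPM of 1 in 3 libraries); leaving out mitochondrially encoded and abundant non-coding RNAs; thinning to the smallest library; DESeq2 1.42.0 and limma-voom; a minimum fold of 1.2; removal of the trend with gene length and GC content (known for 96.1% of tested genes); the block; and leaving out each library. Repeats of these on the paired fit, leaving out each pair, and leaving out both replicate 1 libraries were chosen after the data had been examined.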

Results

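Total RNA was sequenced from SEM, an established human B-cell precursor acute lymphoblastic leukaemia line that carries the KMT2A::AFF1 gene fusion. The cells had been transfected either with a pair of Dicer-substrate short interfering RNAs directed at the back-splice junction of a circular RNA made from the fusion gene and called AK_8_2 (knock-down, KD, 3 libraries) or with a commercial non-targeting duplex (negative control, NC, 3 libraries). A circular RNA is a closed loop in which a downstream splice site is joined to an upstream one, so an siRNA over that junction can be directed at the circle rather than at linear transcripts that share its exons. The counts assigned to genes totalled 16531673, 26694160 and 21186216 in KD replicates 1, 2 and 3, and 14750579, 24186646 and 23453412 in NC replicates 1, 2 and 3. The question posed by the design is which transcripts differ in abundance when AK_8_2 is silenced.

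The replicate 1 libraries of both groups stood apart from the other 4. In replicate 1 of both groups many records fell outside genes: 50.03% of the records of KD replicate 1 and 48.6% of those of NC replicate 1 lay in no annotated feature, against 11.3% to 17.3% in the other 4 libraries. Genes with at least 1 count numbered 53121 and 52077 in these libraries and 30641 to 32311 in the others. The first principal component, with 78.8% of the variance of log2 normalised counts (CPM), separated the replicate 1 libraries of both groups from the rest. KD replicate 3 stood apart in another way, with 31.5% of its records aligned to several places (at most 17.3% elsewhere) and 6.79% of its gene counts on the mitochondrial ribosomal RNAs (at most 1.34% elsewhere).

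**Figure D1:**
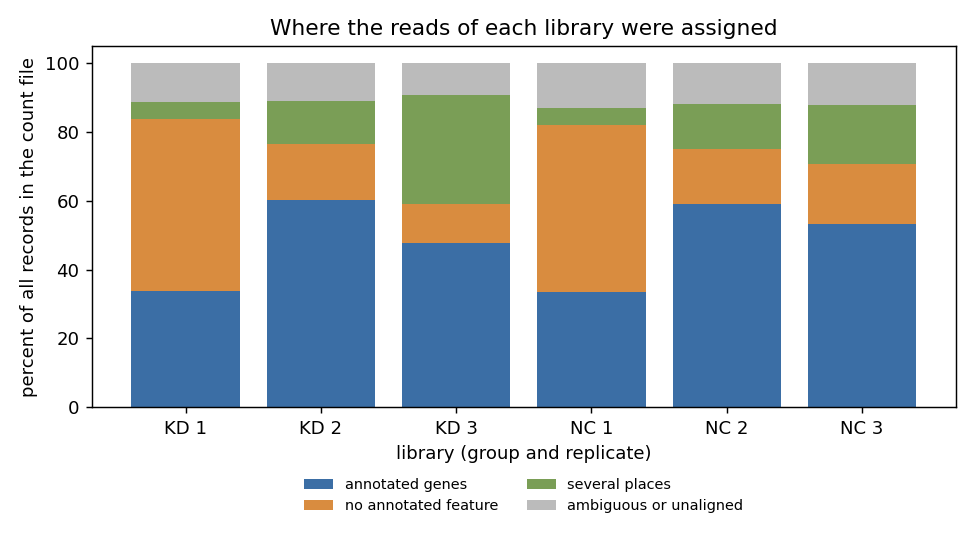
Percent of all records of each count file (y axis) that were assigned to annotated genes, to no annotated feature, to several places, or were ambiguous or unaligned, per library (x axis, group and replicate). The share with no annotated feature was 50.03% in KD replicate 1 and 48.6% in NC replicate 1, and the share aligned to several places was highest, at 31.5%, in KD replicate 3.

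The fusion partner genes showed no detectable difference between KD and NC. KMT2A (ENSG00000118058.24, a histone H3 lysine methyltransferase, chromosome 11, 118436464 to 118526832, plus strand, GRCh38) had 162 ± 18.5 CPM (SD, n = 3) in KD and 170 ± 41.7 CPM (SD, n = 3) in NC, a log2 fold change of -0.07. Its 95% interval ran from -0.51 to 0.37 without the block and from -1.04 to 0.94 with the replicate number as a block. AFF1 (ENSG00000172493.23, a scaffold of the super elongation complex, chromosome 4, 86935002 to 87141054, plus strand) had 212 ± 25.2 CPM (SD, n = 3) in KD and 214 ± 39.8 CPM (SD, n = 3) in NC, a log2 fold change of -0.02. Its interval ran from -0.40 to 0.37 without the block and from -0.20 to 0.18 with it. KMT2A counts were 2680, 4679 and 2908 in KD replicates 1, 2 and 3 and 2457, 3227 and 4985 in NC. Counts of AFF1 were 3299, 6010 and 4068 in KD and 2852, 4815 and 5866 in NC. Within replicate 2 both genes were higher in KD (log2 differences of 0.39 for KMT2A and 0.17 for AFF1), and within replicate 3 both were lower (-0.51 and -0.26). A gene count pools the linear transcripts of both alleles, the fusion transcript and any circular RNA, so these values neither measure AK_8_2 nor show how far it was silenced.

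**Figure D2:**
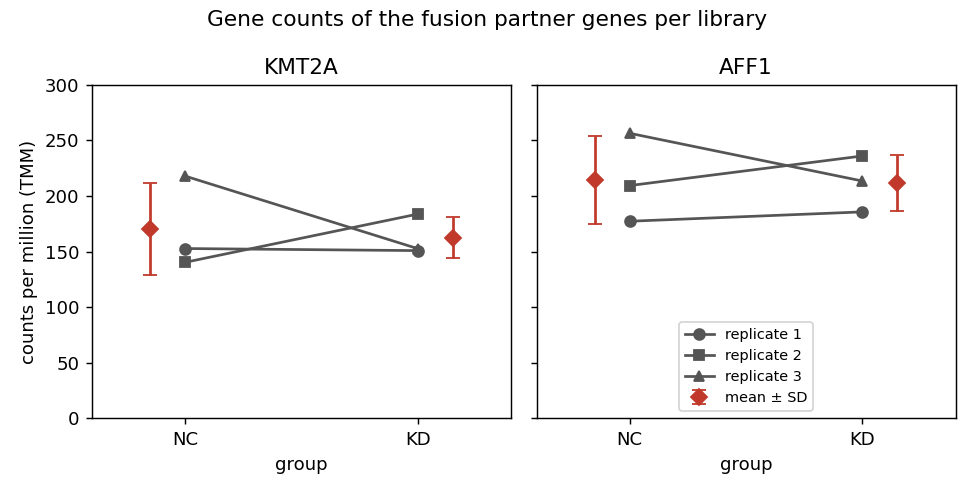
Normalised counts of KMT2A and AFF1 (CPM with TMM factors, y axis) in the NC and KD libraries (x axis), with lines joining libraries of the same replicate number and diamonds giving the mean ± SD of 3 libraries. Both genes were higher in KD in replicate 2 and lower in replicate 3, with KMT2A means of 162 in KD and 170 in NC.

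Without regard to the replicate number, no gene passed the test between KD and NC. Of 16929 genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 52 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. limma-voom also called 0, and DESeq2 called 1, the ribosomal protein pseudogene RPS27AP16 (log2 fold change 0.54, DESeq2 adjusted p 0.00118). The genes with the smallest unadjusted p, none of which passed, were RPS27AP16 (log2 fold change 0.54), RPL7AP6 (0.48), RPL10P9 (0.55), RPL15P3 (0.40) and DPM3, a subunit of dolichol-phosphate mannose synthase (0.45), among those higher in KD. Among those lower in KD they were ABHD3 (-0.30), the single-strand DNA binding protein NABP1 (-0.30), the metalloprotease ADAM28 (-0.32), the sorting nexin SNX14 (-0.29) and RBM18 (-0.24). In simulated counts with the spread of these libraries this fit recovered 56% of genes seeded with a 4-fold change, 16% of those with a 2-fold change and 0% of those with a 1.5-fold change.

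With the replicate number as a block, 29 genes passed, and nearly all of them belonged to a few families. Of the 24 that rose in KD, 20 were processed pseudogenes (reinserted copies of messenger RNAs), 17 of them named as copies of cytoplasmic ribosomal protein genes, and 4 code for proteins. The 5 that fell were all short structured non-coding RNAs. The pseudogenes included RPS23P8 (chromosome X, 70962964 to 70963293, plus strand), at 320 ± 81.7 CPM in KD and 216 ± 46.6 in NC (SD, n = 3 each), with a paired log2 fold change of 0.56 (SE 0.05, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p 8.42e-06). RPS27AP16 (chromosome 16, 61055399 to 61055964, minus strand) had 199 ± 15.7 CPM in KD and 137 ± 6.78 in NC and rose by 0.54 (SE 0.05, edgeR quasi-likelihood, adjusted p 1.76e-05). RPL10P9 rose by 0.55, RPS18P5 by 0.44, RPL15P3 by 0.40, RPS15P4 by 0.39, RPS7P1 by 0.37, RPL6P27 by 0.36 and RPL7P9 by 0.33 on the log2 scale. The 17 rises ranged from 0.24 to 0.56, while the parent genes of these copies had paired log2 fold changes from -0.25 to 0.15. This class, noticed after the calls were seen, had 257 tested members, and their median paired log2 fold change was -0.08. Counts of such copies are uncertain, since a processed pseudogene shares most of its sequence with its parent messenger RNA and a read of one can be placed on the other.

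The risen protein-coding genes included RPS29, a protein of the small ribosomal subunit, RPL27 of the large subunit, and ROMO1, a small protein of the inner mitochondrial membrane. RPS29 (ENSG00000213741.11, chromosome 14, 49570984 to 49599164, minus strand) had 1525 ± 152 CPM in KD and 1229 ± 107 in NC (SD, n = 3 each), a rise of 0.31 on the log2 scale (SE 0.04, edgeR quasi-likelihood, adjusted p 0.00122). RPL27 rose by 0.24 and ROMO1 by 0.32. The 3 other risen pseudogenes were PPIAP22, a cyclophilin A copy (0.45), and the unnamed loci ENSG00000283041.1 (0.30) and ENSG00000264281.3 (0.48), whose parent genes were not identified. These 3 and ROMO1 fall outside the naming rule and were chosen after their values were seen. Among the RNAs that fell, RNU4-1 (chromosome 12, 120293097 to 120293237, minus strand) and RNU4-2 (chromosome 12, 120291763 to 120291903, minus strand), neighbouring genes of the U4 spliceosomal RNA, changed by -0.68 (SE 0.08) and -0.74 (SE 0.10). RN7SL4P, a copy of the signal recognition particle RNA, changed by -0.57, RN7SKP203, a copy of the 7SK RNA, by -0.56, and SNORD3A, the U3 RNA of ribosomal RNA processing, by -0.39. These 5 also belong to families of near-identical copies. RNU4-1 had 10.9, 46.5 and 32.0 CPM in KD replicates 1, 2 and 3 and 16.8, 68.2 and 58.0 in NC.

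**Figure D3:**
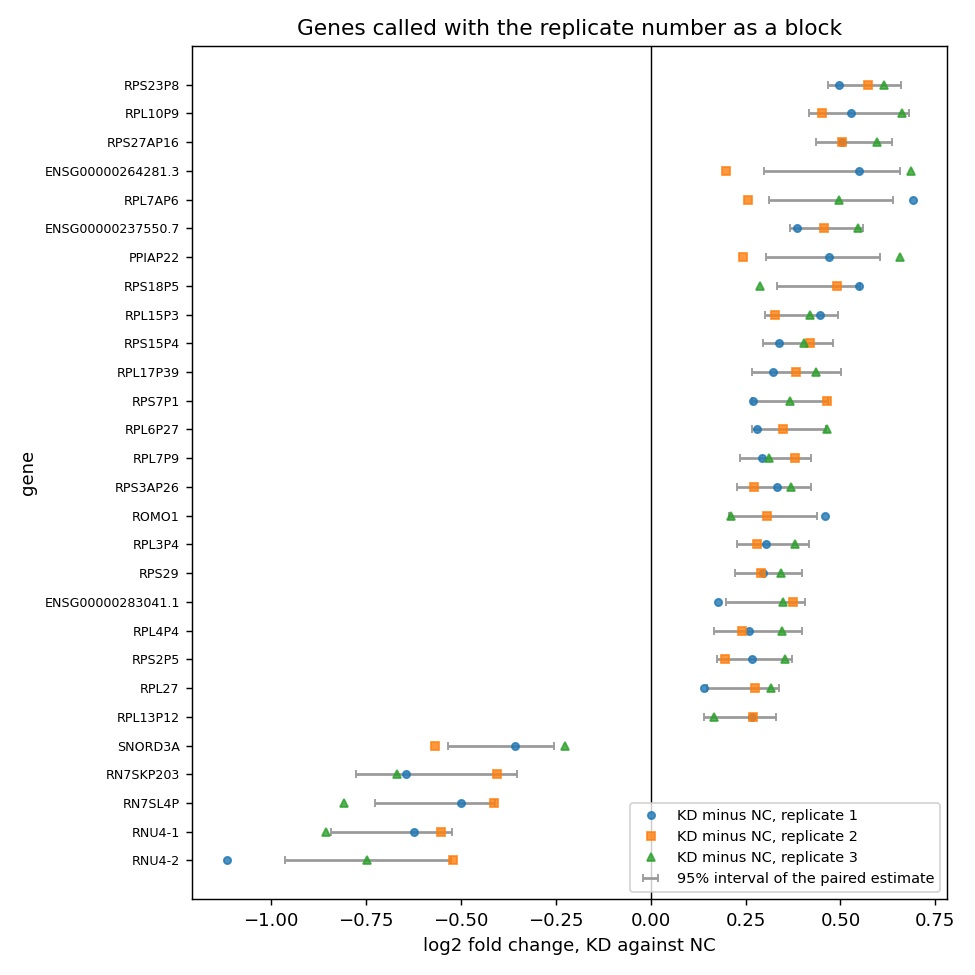
Log2 fold change of KD against NC (x axis) for 28 of the 29 genes called with the replicate number as a block (y axis), as the difference within each replicate number (points) and the 95% interval of the paired estimate (bars). The genes shown moved the same way in the 3 replicate pairs, and their paired estimates lay between 0.24 and 0.74 in absolute log2 fold change.

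All 29 genes moved the same way in all 3 pairs, which is largely built in because they were called on these same differences. Of all tested genes 25.7% did so, against 25% by chance. Leaving out pair 1, 2 or 3 changed the 29 calls to 5, 119 or 73, of which 4, 25 and 25 were among the 29. Simulated counts with no changed gene gave 7 to 25 calls in 5 draws with each gene's own estimated dispersion and 0 calls in 5 draws with the trended dispersion, and 841 genes had an unadjusted p under 0.05 where chance gives 846. The adjusted p values of the paired calls may therefore be too small. Of all tested genes, 66.6% had a paired 95% interval inside a 1.5-fold change in either direction.

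Cytoplasmic ribosomal protein genes, the components of the ribosome, were shifted upward by a small amount. Of 79 tested members 66 had a higher paired estimate in KD, the median was 0.08, and the medians within pairs 1, 2 and 3 were 0.06, 0.08 and 0.10. The list passed camera with a preset inter-gene correlation, with adjusted p 1.11e-06 without the block and 1.05e-06 with it, but not with an estimated correlation (adjusted p = 0.977 and 0.757 with an estimated correlation). 3 members rose over all genes tested, RPS29 and RPL27 among them, and adjusted over the list alone 20 rose and 1 fell, all with the block. Without it the counts were 0. Nuclear oxidative phosphorylation genes, which encode subunits of the respiratory chain and ATP synthase, had a paired median of 0.08 over 60 members, 48 of them higher in KD, with medians of 0.04, 0.07 and 0.08 within the pairs. Their camera adjusted p was 7.54e-05 without the block and 8.43e-06 with it (adjusted p = 0.977 and 0.757 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 8 rose with the block and 0 without it. The members with the smallest p were COX7A2, a subunit of cytochrome c oxidase (log2 fold change 0.22, edgeR quasi-likelihood adjusted p 0.103), and NDUFAB1, the mitochondrial acyl carrier protein (0.25, adjusted p 0.171). All random lists had a lower paired median than the ribosomal and the oxidative phosphorylation list. Without the block, and with KD replicate 3 left out, camera placed both lists lower in KD than the other tested genes (camera adjusted p 0.0246 and 0.0283 for the ribosomal and the oxidative phosphorylation list). That fit tested 31605 genes rather than 16929, with a median log2 fold change of 0.10 over all genes. This direction alone therefore does not show a fall of the lists. Still without the block, both calls ended without KD replicate 2 (0.209 and 0.205), without NC replicate 1 (0.952 and 0.818) or with no filter on low counts (0.141 and 0.223). The fits without KD replicate 2 and with no filter also tested more genes (31474 and 56716). With the block, both calls ended without pair 2 (camera adjusted p 0.284 and 0.377), without pair 3 (0.290 and 0.279) or with no filter (0.0931 and 0.127). These fits tested 29982, 29966 and 56716 genes rather than 16929, so the genes that the lists were compared with changed too. Without pair 1, with 16344 genes tested, both lists stayed called.

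Lists of histone genes and abundant non-coding RNAs were lower in KD and passed camera with the block but not without it. Replication-dependent histone genes, whose messenger RNAs lack poly(A) tails, had a paired median of -0.09 over 52 tested members, of which 2 were higher in KD. The camera adjusted p values were 0.0935 without and 2.81e-06 with the block (adjusted p = 0.771 with the block and an estimated correlation). Their medians within pairs 1, 2 and 3 were -0.02, -0.01 and -0.27, and leaving out pair 3 ended the call (camera adjusted p 0.725). The KD library of that pair had 31.5% of its records aligned to several places and 6.79% of its gene counts on the mitochondrial ribosomal RNAs, against at most 17.3% and 1.34% elsewhere. No histone gene passed over all genes. With the block, but not without it, 1 fell adjusted over the list alone, H4C2, at -0.22 (edgeR quasi-likelihood adjusted p 0.239 over all genes), and H4C1 stood at -0.23. The abundant non-coding RNAs had a paired median of -0.24 over 13 tested members (camera adjusted p 0.346 without and 0.00104 with the block; adjusted p = 0.757 with the block and an estimated correlation), with RNU4-1 and RNU4-2 as the 2 called members both over all genes and adjusted over the list alone, with the block and not without it. Their medians within the pairs were -0.07, -0.41 and -0.53, the lowest again in the pair of that library, and leaving out pair 2 or pair 3 ended this call too (camera adjusted p 0.137 and 0.0921). The fits without pair 2 and pair 3 tested 29982 and 29966 genes rather than 16929. Without pair 1 the histone and the non-coding RNA list stayed called. None of the random lists had a lower paired median than the histone or the abundant non-coding RNA list.

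**Figure D4:**
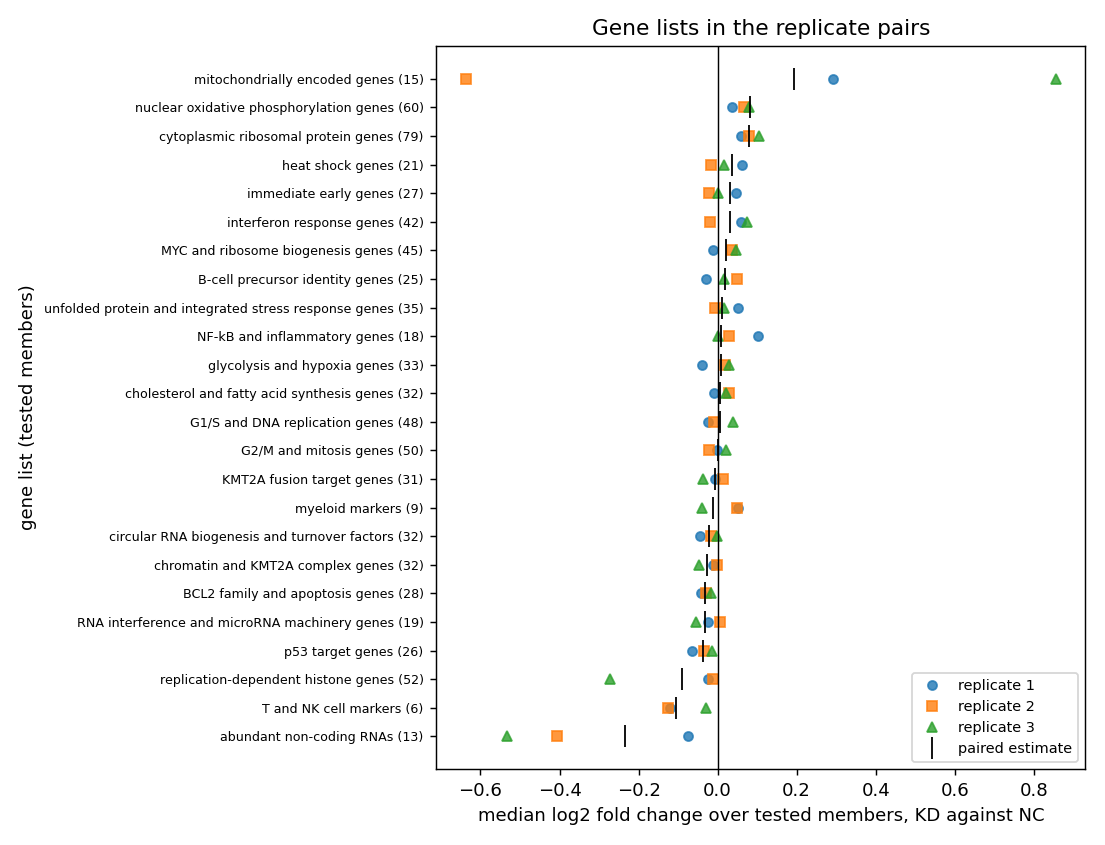
Median log2 fold change of KD against NC (x axis) over the tested members of each of the 24 gene lists with at least 5 tested genes (y axis, number tested in brackets), within each replicate pair (points) and from the paired estimate (ticks). Ribosomal protein and oxidative phosphorylation genes lay above 0 in all 3 pairs, at 0.04 to 0.10, and the mitochondrially encoded genes went from -0.64 in pair 2 to 0.86 in pair 3.

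Lists of genes tied to the KMT2A fusion and to the identity of the leukaemia did not pass camera. KMT2A fusion target genes, which include the HOXA cluster, MEIS1 and other genes bound by KMT2A fusion proteins, had a paired median of -0.01 over 31 tested members, none called over all genes, and the list did not pass camera (adjusted p 0.931 without and 0.943 with the block). Of these, 28 had a paired 95% interval inside a 1.5-fold change. LGALS1, encoding galectin 1, was the 1 member past the threshold adjusted over the list alone, with the block and not without it (paired log2 fold change 0.20, edgeR quasi-likelihood adjusted p 0.185 over all genes), and HOXA3 stood at -0.21. B-cell precursor identity genes had a paired median of 0.02 over 25 members and did not pass camera (adjusted p 0.374 without and 0.271 with the block). IGLL1, a component of the surrogate light chain, was past the threshold adjusted over the list alone with the block only (0.27, edgeR quasi-likelihood adjusted p 0.344 over all genes), and CD79A, a signalling chain of the B-cell receptor, stood at 0.16. Chromatin and KMT2A complex genes had a paired median of -0.03 over 32 members (camera adjusted p 0.910 without and 0.660 with the block), with PSIP1, which tethers KMT2A to chromatin, at 0.14 and MLLT10 at 0.10, and none was called. Of the random lists, 1.51% had a lower paired median than this list, and 1.34% a lower one without the block. The paired shares were 19.1% for the fusion targets and 80.2% for the B-cell precursor genes.

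No list of cell cycle, growth or death genes passed camera, with or without the block. With the block the camera adjusted p was 0.868 for G1/S and DNA replication genes (48 tested, CHAF1B at 0.13), 0.914 for G2/M and mitosis genes (50 tested, PTTG1 at 0.13) and 0.259 for MYC and ribosome biogenesis genes (45 tested, median 0.02, NME1 at 0.19). It was 0.316 for p53 target genes (26 tested, median -0.04, RRM2B at -0.19) and 0.271 for BCL2 family and apoptosis genes (28 tested, median -0.03, CFLAR at -0.19). Of the G1/S genes 47 and of the G2/M genes 48 had a paired 95% interval inside a 1.5-fold change. No member of these lists was called over all genes or adjusted over the list alone. A lower paired median was found in 4.07% of random lists for the BCL2 family list and 7.48% for the p53 list. The shares for the other lists here were 36.5% to 91.5%.

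Lists of responses to double-stranded RNA and stress, and of the machinery of RNA interference and circular RNA, did not pass either. Interferon response genes had a paired median of 0.03 over 42 tested members (camera adjusted p 0.259 with the block), with IFITM3 at 0.40 and ISG15 at 0.26, both uncalled (edgeR quasi-likelihood adjusted p 0.607 and 0.888). NF-kB and inflammatory genes (18 tested, TNIP1 at 0.13) had a camera adjusted p of 0.349 and immediate early genes (27 tested, KLF2 at -0.31) one of 0.596. The values were 0.548 for unfolded protein and integrated stress response genes (35 tested, ATF4 at 0.13), 0.333 for glycolysis and hypoxia genes (33 tested, ALDOC at 0.19) and 0.596 for cholesterol and fatty acid synthesis genes (32 tested, ACAT2 at 0.12). Heat shock genes had 0.206 over 21 tested members, with HSPE1, a mitochondrial chaperonin, past the threshold adjusted over the list alone, with the block only, at 0.29 (edgeR quasi-likelihood adjusted p 0.0821 over all genes). RNA interference and microRNA machinery genes (19 tested, median -0.03, TNRC6A at -0.09) had 0.486, and circular RNA biogenesis and turnover factors (32 tested, median -0.02, DDX39A at 0.13) had 0.473. Of the random lists, 2.46% had a lower paired median than the RNA interference list and 0.69% than the circular RNA list. Without the block the shares were 1.57% and 0.84%. For the other lists here the paired shares were 56.9% to 96.1%.

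No marker of another blood cell type was called, with or without the block. Enough counts to be tested were found for 9 of 22 myeloid markers, 6 of 23 T and NK cell markers and 4 of 20 erythroid and megakaryocytic markers. The globin genes of the erythroid list, such as HBB, do not bear on this, because the library kit depletes their transcripts. The myeloid list had a camera adjusted p of 0.660 with the block (SPI1 at 0.10, VCAN at -0.10), and the T and NK list one of 0.154, with ZAP70 at -0.10 and GZMA at -0.58. GZMA was near the floor, at 0.26 to 1.35 CPM per library. The fry test, which asks whether the genes of a list move one way on balance, gave the T and NK list an adjusted p of 0.0485 with the block and 0.999 without it. Of the random lists, 2.36% had a lower paired median than the T and NK list and 42.6% than the myeloid list. Without the block the shares were 1.92% and 84.7%. The erythroid list was too short to be tested as a list, with EPOR at -0.38 and ITGA2B at 0.31, neither called. EPOR had 2.93 CPM in KD replicate 1 and 4.35 in NC replicate 1, against 0.22 to 0.74 in the other libraries. ITGA2B had 5.35 and 3.73, against 0.43 to 0.63.

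The 15 mitochondrially encoded genes differed in opposite directions between pairs. Their median log2 difference was 0.29 in pair 1, -0.64 in pair 2 and 0.86 in pair 3, and the list did not pass camera with or without the block (adjusted p 0.259 and 0.0935). All random lists had a lower median than this list in both fits, although its pairs disagreed in direction. MT-RNR1, the small mitochondrial ribosomal RNA, stood at -0.15, -0.21 and 1.62 in the 3 pairs.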

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

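The tests of genomic DNA, strand and unspliced RNA on silent genes were written down before their values were computed, and the comparison with no filter on counts was chosen only after these were seen. In reads outside the gene counts, 50.03% of the records of KD replicate 1 lay in no annotated feature, above the highest control library, NC replicate 1, at 48.6%. The pattern is in both groups: these replicate 1 libraries also had counts on 10998 (KD) and 10411 (NC) of 18413 genes that had no count in any of the other 4 libraries. Reads counted on the opposite strand would pile up across from expressed genes, where the density over silent genes was at most 1.55 times that over silent genes at least 50 kb from any tested gene. Unspliced RNA would favour silent genes inside tested genes, where it was at most 0.747 times that of the isolated ones (isolated over inside at least 1.34). Leaving out every gene with a count in another library also leaves out genes that collect intronic or opposite-strand reads, so these ratios decide nothing. With no such filter, over 4 sets of gene types and 2 summaries, the excess of the replicate 1 libraries inside tested protein-coding genes was 0.991 to 4.996 times that at isolated genes in 56 comparisons, 30 of them at 2 or more, and opposite such genes 1.502 to 2.75 times, 20 of them at 2 or more; 8 further comparisons had no ratio because the isolated median was 0. The isolated silent genes still had 4.57 (KD) and 4.13 (NC) reads per kb, which neither introns of tested genes nor reads across from them supply, so genomic DNA, with or without either of these, remains a candidate explanation, and no biological explanation was tested since the pattern spans both groups.

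In KD replicate 3, 31.5% of the records were aligned to several places, above the highest control library, NC replicate 3, at 17.3%.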

How the results depend on the processing

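The repeats on the paired fit, and the fits without both replicate 1 libraries, were chosen after the data had been examined. The count of 0 genes without the block held under every other normalisation, filter, thinning, limma-voom, the 1.2-fold minimum, the length and GC correction and each left-out library (0 to 0); DESeq2 called 1, the replicate block 29 and the replicate block with the length and GC correction 25. Without both replicate 1 libraries edgeR called 0 (253 at an unadjusted p under 0.05), and 5 with the block. The 29 paired calls became 18 with library totals only, 68 with no filter, 19 with limma-voom, 3 with a 1.2-fold minimum, 5, 119 and 73 without pair 1, 2 or 3, and 0 with no block; all 29 were among the 68, and the genes kept without pair 1 were RNU4-2, RPS27AP16, RPS23P8 and ENSG00000237550.7, a copy of RPL9. More genes were tested without pair 2 or 3 (29982 and 29966), because the replicate 1 libraries then weigh more in the filter. All 29 genes kept their direction in every paired alternative that tested them.

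The 2 lists called without the block became 0 with an estimated correlation, 0 with fry, 4 with library totals only, 4 with the block, 5 with the block and the length and GC correction, 4 without both replicate 1 libraries with or without the block, and 6 to 15 with 1 library left out, where the share of replicate 1 libraries differs between the groups; neither of the 2 was among those called without KD replicate 2 (14), without NC replicate 1 (6) or with no filter (2). The 4 lists called with the block became 0 with an estimated correlation, 1 with fry, 2 with no filter, 2 without pair 2, 0 without pair 3 and 2 with no block. The 1 list called by fry, the T and NK list, was not among the 4, whose fry adjusted p values were 0.292 to 0.567. Of the 2 lists called without pair 2, 1 was among the 4. All 4 stayed called without pair 1. The cause of these differences was not tested. Among named genes, no call reversed direction; summed over these genes and all alternatives, their calls were lost 67 times and gained 8 times in the paired fit, and gained 17 times and lost 0 times without the block. Beyond the calls given with and without the block beside each result, it changed none. Gene counts do not resolve circular RNA at any depth.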

Other observations

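The tests of shared variation within lists, of the other splits of the libraries, and of the length and GC trend on the called pseudogenes were chosen after the results were seen. The estimates for copies of ribosomal protein messenger RNAs went with their abundance, a difference that was not tested. Of the 257 tested ribosomal protein pseudogenes, 116 had a higher paired estimate in KD and the median was -0.08. The medians within pairs 1, 2 and 3 were -0.03, 0.06 and -0.22, so the class as a whole had no rise shared by the pairs. Of the 36 with a mean of at least 30 CPM, 35 had a higher estimate and the median was 0.27. The lowest mean among the 17 that rose was 44.4 CPM. Their median rise was 0.38, against a median of 0.03 for their parent genes, and all 17 lay above their parent. The 17 were picked for their own rise, so this contrast with the parents is partly built in.

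The tables argue against a trend with gene length or GC content: after its removal per library the median of the 17 was 0.41, and 16 of them stayed called. The call of RPL4P4 ended at an unchanged log2 fold change of 0.28 as its SE went from 0.0554 to 0.0570 (adjusted p 0.0459 before and 0.0683 after). Reads of parent genes placed on their copies at a different rate would also lift copies of other abundant genes. The 322 tested copies of other genes with a parent at 100 CPM or more had a median -0.18 relative to the parent (95% bootstrap interval -0.233 to -0.121). The interval resamples copies, so it does not measure the spread between libraries. The copies' own median log2 differences were -0.08, 0.07 and -0.32 in pairs 1, 2 and 3. The comparison was also a poor one because 250 of the 322 had 3 CPM or less, while the copies that rose had at least 44.4. Only 8 of these other copies reached 30 CPM; 6 of the 8 lay above their parent, with a median difference of 0.03, and PPIAP22 was called, though not after the length and GC correction (log2 fold change 0.45 before and 0.48 after, SE 0.0706 and 0.0842, adjusted p 0.0683 after). Placement of parent reads therefore cannot be told apart from a change in the copies themselves, because too few abundant copies of other genes exist, and an effect of silencing AK_8_2 stays open and untested by any other value here.

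The median shift of ribosomal protein and oxidative phosphorylation genes was not removed by the length and GC correction: the median of both lists together was 0.0805 after it and 0.0810 before, and both lists stayed past the camera threshold. The single-gene calls were less stable, as 1 of the 3 called ribosomal protein genes, RPS29, stayed called. RPL27 had a log2 fold change of 0.24 before and after, and its call ended as its SE went from 0.0451 to 0.0521 (adjusted p 0.0275 before and 0.106 after). Members of each list varying together between libraries may account for the calls. The smaller camera adjusted p of the pair of lists rose to 0.757 when the correlation was estimated. No list passed with an estimated correlation in either fit, so this loss cannot tell shared variation from low power with 6 libraries. An effect of the silencing stays open as well.

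Of the 5 non-coding RNAs that fell, 3 stayed called after the length and GC correction. RNU4-2 went from -0.74 (SE 0.0961) to -0.60 (SE 0.102, adjusted p 0.106), so its call ended with a smaller estimate. SNORD3A stayed at -0.39, and its call ended as its SE went from 0.0654 to 0.0730 (adjusted p 0.0749).

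Other splits of the libraries are too few for a share under 0.05. Among the 10 splits of the 6 libraries into groups of 3, edgeR called 0 genes in the real one and at most 0 in the others, so 10 of 10 gave as many. For the gene lists without the block the real split called 2 and the highest other 17, and 7 of 10 gave as many; the 4 splits with both replicate 1 libraries on the same side called 13 to 17 lists, which points to the structure by replicate number. Among the 4 splits that part every replicate pair, the real one called 29 genes and the highest other 9, so 1 of 4 gave as many, and the real one called 4 lists and the highest other 4, so 2 of 4 gave as many.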
